A study of Mus musculus with 6 samples.

How the data were processed

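Gene expression was measured by RNA-seq in fibroadipogenic progenitors (FAPs) from peripheral blood and from muscle of mice with middle cerebral artery occlusion (MCAO). Per the labels, RNA was extracted with RLT plus buffer and libraries were made with a TruePrep DNA Library Prep Kit, in which a transposase fragments and tags double-stranded DNA. The authors deposited 1 table of raw counts of reads per gene symbol, with 1 column for each of 3 circulating and 3 muscle samples. Per the submitters' processing notes, Trim Galore, STAR and featureCounts were used with the mouse build GRCm39; their versions, options and the annotation were not given. The reference at hand was GRCm38 with the GENCODE M21 annotation, so no coordinates are given, and only exon lengths were taken from it, matched by symbol for 91.2% of the symbols.

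The table held 33276 genes, of which 1742 had no read in any sample. Rn18s and Rn18s-rs5, both 18S ribosomal RNA, had identical counts in each sample, so the same 18S reads appear under both symbols and are counted under both in the totals. Of 12777 genes with at least 200 reads, 134 had 6 counts equal to those of another gene. Totals ran from 5522193 to 13813329 counts in the circulating samples and from 17532558 to 23424039 in the muscle samples. The common dispersion was 0.381. The steps were tested on counts simulated from the means, library sizes and dispersions of these samples, with changed genes at a mean of at least 20 counts per 1000000. Of 50 genes changed at each size, the test recovered 2% at 2-fold, 8% at 4-fold, 22% at 8-fold and 56% at 16-fold, with 4 false calls among 48.

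Samples were grouped by their labels. Replicates were compared before averaging, and the chi-square statistic per degree of freedom between samples of one group lay between 67.8 and 104, far beyond sampling noise. The labels do not say that samples of one group came from separate mice, so p-values measure the spread between these samples, which may be technical. The groups share replicate numbers, but no label says that a number marks the same mouse, and the fit had no pairing term.

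Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a robust fit, trimmed mean of M values (TMM) scaling and the default filterByExpr filter, which left 20248 genes. Fold changes are log2, circulating minus muscle. Their standard error is the coefficient divided by the square root of its F statistic. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are counts per 1000000 (CPM) of the TMM-scaled library size, as mean ± SD over the 3 samples of a group.

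Before the data were examined, 33 gene lists with 862 genes were written, 16 of the genes in more than 1 list. They cover FAP identity, matrix, signalling, cell state, RNA quality and markers of other cell types. Lists with at least 5 tested genes were tested with camera (limma 3.58.1), which sets a list against all other tested genes, at a preset correlation of 0.01 and with adjustment over the lists. The same test with an estimated correlation stands beside each call. In simulated data a 2-fold fall of the collagen list gave adjusted p = 1.28e-06 with the preset and adjusted p = 0.123 with an estimated correlation, and no other list was called. The simulated genes were drawn independently of each other, so this cannot show how the preset limits false list calls where genes vary together. In the real data the estimated correlation was 0.0595 for collagens and 0.622 for cytosolic ribosomal proteins. Members were counted past the threshold over all genes and adjusted over the list alone.

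The rule for named genes took, in each direction, up to 8 genes with the largest fold change among those past the threshold, without overlap between the groups and at a mean of at least 50 CPM in the higher group, leaving out predicted models. It added 6 surface markers commonly used to sort FAPs. From each list it took up to 3 members past the threshold, the most abundant first, or else the most abundant member. This gave 48 genes, 15 of them past the threshold. All other genes named were chosen after their values were seen, most of them because they passed the test adjusted over their list alone.

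Shares of counts and numbers of detected genes were compared with two-sided exact permutation tests of the difference of means. For detected genes, libraries were thinned to the smallest total. A background of reads was estimated per library from vomeronasal, taste and trace amine receptor genes, which are silent outside sensory tissue, as the median over these genes of reads per kilobase of exon, scaled to reads per 1000000 without 18S. Of 591 such genes, 556 had an exon length. A level over background is a gene's reads per 1000000 without 18S divided by the background expected for its exon length.

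Other settings tried were different scalings (RLE size factors, TMMwsp, upper quartile, library size), no filter, a filter of at least 5 CPM in at least 3 samples, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, haemoglobin and mitochondrial genes removed, a test against a log2 change of 1, a threshold of 0.01, fry for the lists, and each sample left out in turn. Settings chosen after seeing the data were removal of 18S, 18S reads counted once, TMM factors from genes with a mean of at least 20 CPM (called scaling on abundant genes here), the 7471 genes at 5 or more times background with 18S removed, thinning to equal totals without 18S, and removal of the trend with abundance from the statistic of camera by a loess fit (span 0.3). Figures were drawn with matplotlib 3.10.9.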

Results

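FAPs are mesenchymal cells that lie between muscle fibres and can give rise to fibroblasts and adipocytes. The series set FAPs from peripheral blood beside FAPs from muscle in mice with MCAO, a model of ischaemic stroke in which an artery of the brain is blocked. Read counts per gene came from 3 circulating and 3 muscle libraries, and no library of mice without the occlusion was analysed. Circulating replicates 1, 2 and 3 held 13813329, 5522193 and 10616808 counts, and muscle replicates 1, 2 and 3 held 19414675, 17532558 and 23424039. The question is how the transcriptome of circulating FAPs differs from that of FAPs resident in muscle.

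18S ribosomal RNA took 48.9% ± 9.69 (SD, n = 3) of counts in circulating and 30.8% ± 2.62 in muscle libraries. The same 18S reads stood under 2 symbols, and this share and the totals count them under both; counted once, 18S took 32.8% ± 8.85 and 18.2% ± 1.81. There were 7880709, 3106011 and 4233124 counts other than 18S in circulating replicates 1, 2 and 3, against 13137875, 12663430 and 15864333 in muscle replicates 1, 2 and 3. Mitochondrially encoded transcripts held 0.636% ± 0.182 of circulating and 1.11% ± 0.222 of muscle counts. For 18S and for mitochondrial transcripts the groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest this design allows, or 0.17 after adjustment over 17 library measures. Of the counts without 18S, mitochondrial transcripts held 1.23% ± 0.139 and 1.61% ± 0.372, and the groups overlapped (exact permutation p = 0.3). Haemoglobin transcripts, a sign of red cells, held 0.0356% ± 0.00981 and 0.0278% ± 0.0183 (exact permutation p = 0.6). Cytosolic ribosomal protein transcripts held 5.32% ± 2.21 and 5.45% ± 0.134 (exact permutation p = 1), with 7.85% in circulating replicate 1 against 4.41% and 3.72% in circulating replicates 2 and 3. The 10 most abundant genes, 18S among them, held 53.1% ± 9.21 and 38.7% ± 2.17 (exact permutation p = 0.1), and 9.12% ± 0.727 and 12.4% ± 0.148 of the counts without 18S. Thinned to equal totals with 18S included, circulating libraries had 26637 ± 449 and muscle libraries 25047 ± 1055 detected genes (exact permutation p = 0.2). Thinned without 18S, they had 26844 ± 293 and 24340 ± 1037 (exact permutation p = 0.1). Spearman correlations across genes, which are not independent replicates, were 0.855 to 0.867 within muscle, 0.786 to 0.796 within circulating and 0.769 to 0.810 between the groups.

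In edgeR with TMM scaling 22 of 20248 genes tested passed the threshold, 21 lower and 1 higher in circulating FAPs, and 4 of the lower genes passed with scaling on abundant genes. Mgp, the matrix Gla protein that inhibits calcification, fell from 3059 ± 619 CPM in muscle to 254 ± 55.4 CPM in circulating FAPs (SD, n = 3), a log2 fold change of -3.59 ± 0.30 (SE; adjusted p = 0.00366). Meox1, a homeobox transcription factor, fell from 69.5 ± 17.9 to 0.722 ± 0.422 CPM (-6.55 ± 0.79, adjusted p = 0.0341). Smoc2, a matricellular protein, fell from 2537 ± 182 to 539 ± 180 CPM, and Col15a1, a collagen of basement membrane zones, from 642 ± 109 to 96.9 ± 29.4 CPM.

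The lower genes with the largest fold changes by the rule, besides Meox1 and Mgp, were Clec11a, a secreted growth factor (-4.77 ± 0.67), Mmadhc, which acts in vitamin B12 metabolism (-4.32 ± 0.61), Gdf10, a member of the TGF-beta superfamily (-4.25 ± 0.56), F3, the tissue factor that starts coagulation (-3.41 ± 0.52), Lhfpl6 (-3.26 ± 0.46) and Hnrnph1, an RNA-binding protein (-3.06 ± 0.46). Gdf10 fell from 247 ± 106 CPM to 19.2, 10.2 and 9.55 CPM in circulating replicates 1, 2 and 3, and F3 from 165 ± 26.5 to 15.5 ± 7.11 CPM. Lpl, the lipoprotein lipase, fell from 966 ± 196 to 178 ± 34.9 CPM (-2.44 ± 0.32). Gsn, the actin-severing gelsolin, fell from 33310 ± 3785 to 14589 ± 1501 CPM (-1.19 ± 0.17). With scaling on abundant genes the log2 fold change of Gsn was -0.46 and did not pass (adjusted p = 0.119 in edgeR). The remaining lower genes were Fosb, Thbs1, Cxcl14, Cyp2f2, Cst3, Emp1, Ifi203, Penk and Gas1, with log2 fold changes between -1.91 and -5.98. The higher gene was Gm10222, a predicted model outside the rule and chosen after its values were seen, at 16.6 ± 5.27 against 0.534 ± 0.164 CPM (4.93 ± 0.74, adjusted p = 0.0469). The 22 genes had no overlap between the groups, as had 5601 of the tested genes (27.7%, where chance gives 10% for 3 against 3). At an unadjusted p under 0.05 there were 1966 genes higher and 1952 lower.

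The count of 22 genes became 65 without circulating replicate 1, 1 (Mgp) without circulating replicate 2, circulating replicate 3, muscle replicate 1 or muscle replicate 2, and 0 without muscle replicate 3, where Mgp had adjusted p = 0.0647 in edgeR; over all settings tried the adjusted p of Mgp ran from 4.09e-11 to 0.0647. With scaling on abundant genes, 7 genes passed, 4 lower (Mgp, Meox1, Emp1 and Smoc2) and 3 higher (C3, Efemp1 and Gm10222), and with DESeq2 1364 were lower and 160 higher.

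**Figure D1:**
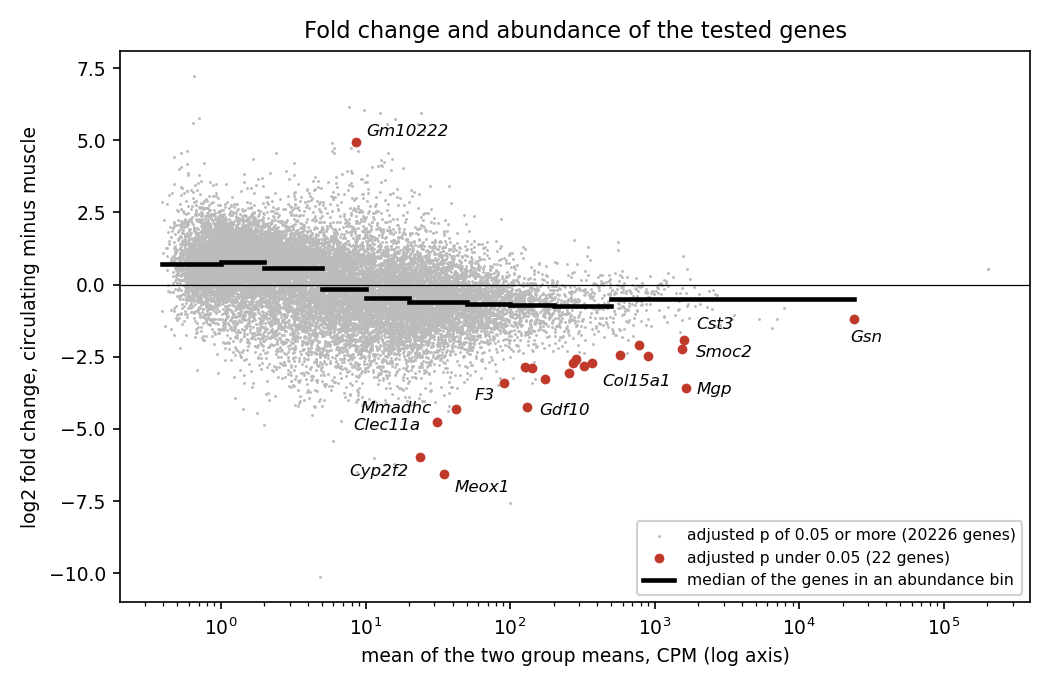
Log2 fold change (circulating minus muscle) of each of the 20248 tested genes against the mean of its group means in CPM on a log axis, with the 22 genes past the threshold in red and the median of each abundance bin as a black bar. Bin medians run from 0.80 at 1 to 2 CPM to -0.75 at 200 to 500 CPM, and the 21 lower genes lie below the median of their bin.

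Fold changes fell with abundance over the tested genes. The median log2 fold change was 0.77 for 6540 genes under 2 CPM, -0.65 for 4736 genes of at least 20 CPM and 0.15 for all genes. Scaling on abundant genes moved the median of all genes by 0.70, upper quartile scaling by 0.67, library size by 0.15 and RLE size factors by -0.10. The directions given here for single genes and lists, and the counts of members over all genes where no other tool is named, are those of edgeR with TMM scaling. The list tests set a list against all other genes; with scaling on abundant genes the ribosomal protein list lost its call (adjusted p = 0.591) and the other 18 lists kept theirs. With an estimated correlation none of the 19 lists passed (adjusted p = 0.163 to 0.702).

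Pdgfra, the receptor that marks FAPs, was at 202 ± 16.5 CPM in circulating and 610 ± 210 CPM in muscle FAPs and did not pass over all genes in edgeR (-1.60 ± 0.35, adjusted p = 0.114) but did with DESeq2 (adjusted p = 0.00989). Cd34 was at 901 ± 103 and 1060 ± 268 CPM (-0.23 ± 0.28, adjusted p = 0.644), and Ly6a, which encodes the sorting antigen Sca-1, at 948 ± 703 and 1335 ± 429 CPM (-0.49 ± 0.47, adjusted p = 0.553). The sign of the Cd34 and Ly6a values turned with scaling on abundant genes, at 0.49 and 0.16. Pdgfra stayed lower with that scaling, at -0.87 (adjusted p = 0.108 in edgeR). Genes of surface markers commonly used to exclude other cells were low in both groups. Ptprc, the pan-leukocyte CD45 gene, was at 11.7 ± 2.38 CPM in circulating and 6.41 ± 1.64 CPM in muscle FAPs (adjusted p = 0.431). Each circulating library (8.98, 12.5 and 13.5 CPM) lay above each muscle library (7.89, 6.70 and 4.64 CPM) for Ptprc. Of all tested genes 27.7% likewise had no overlap. With scaling on abundant genes the log2 fold change of Ptprc was 1.59 (adjusted p = 0.143 in edgeR). The endothelial Pecam1 was at 6.42 ± 3.20 and 13.5 ± 8.11 CPM (adjusted p = 0.431), and the satellite cell integrin Itga7 at 5.20 ± 4.17 and 11.2 ± 5.74 CPM (adjusted p = 0.416).

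FAP and mesenchymal progenitor identity genes went in both directions. Of 35 members 4 fell over all genes tested (Smoc2, Cxcl14, Gsn and Meox1) and none rose in edgeR (8 and 1 with DESeq2), while 7 fell and 3 rose adjusted over the list alone. Pdgfra, Pdgfrb (-2.37 ± 0.55) and Tnfaip6 (-1.25 ± 0.30) were the further lower members. The higher members were Dpp4, a surface peptidase of early mesenchymal progenitors, at 142 ± 63.3 against 29.7 ± 7.02 CPM (2.26 ± 0.53), Efemp1, a fibulin, at 412 ± 68.5 against 143 ± 41.8 CPM (1.53 ± 0.37), and Pi16, a marker of a fibroblast population shared by many tissues, at 823 ± 443 against 297 ± 109 CPM (1.47 ± 0.47). Over all genes Dpp4, Efemp1 and Pi16 did not pass in edgeR (adjusted p = 0.127, 0.129 and 0.180). Dpp4 did with DESeq2 (adjusted p = 0.00651). The list was lower than other genes (adjusted p = 0.00201; adjusted p = 0.212 with an estimated correlation), but its median of -0.35 was 0.29 with scaling on abundant genes, 0.28 with upper quartile scaling and -0.77 without circulating replicate 1. With the trend with abundance removed the list lay on the higher side and did not pass (adjusted p = 0.338). With scaling on abundant genes 8 members were higher and 5 lower adjusted over the list alone, and under TMM 1 member was higher without muscle replicate 2 and 1 without muscle replicate 3.

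**Figure D2:**
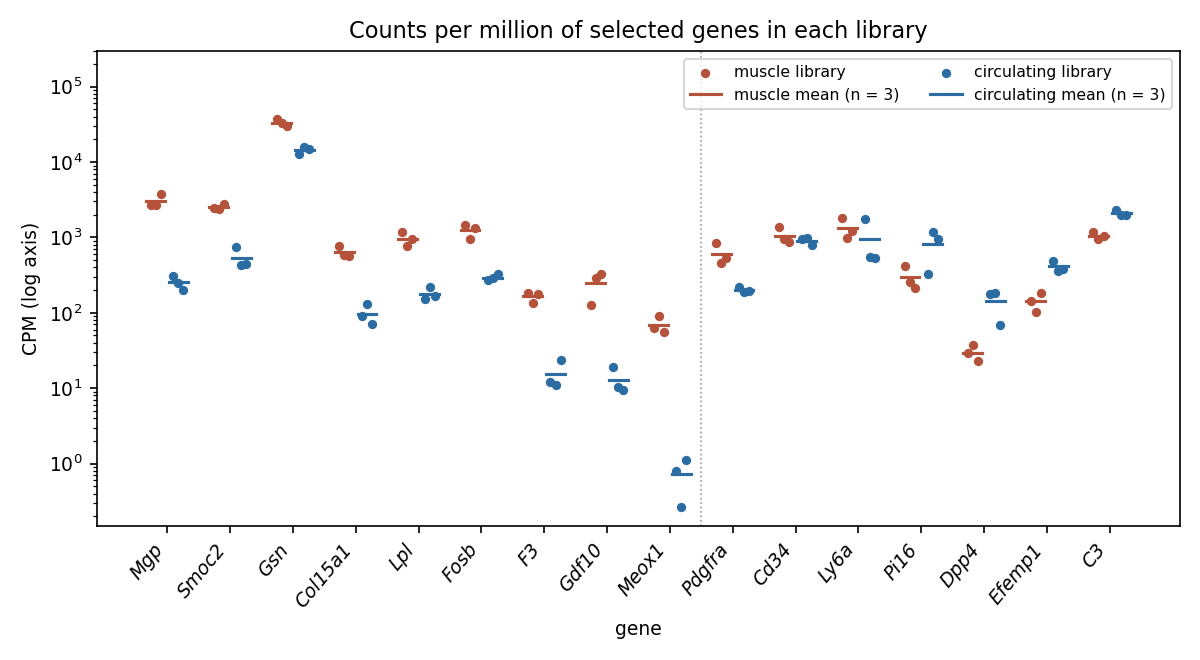
Level of 16 genes in each library, in CPM on a log axis, with muscle libraries in red, circulating libraries in blue and a bar at each mean (n = 3). The 9 genes left of the dotted line passed the threshold in edgeR with TMM scaling as lower in circulating FAPs; the 7 to its right did not pass there, and among them Dpp4, Efemp1 and C3 lie higher in each circulating than in each muscle library.

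The adipogenic list had 1 of 27 members lower over all genes in edgeR (Lpl; 3 with DESeq2) and 3 adjusted over the list alone. The others were Scd1, a fatty acid desaturase (-1.53 ± 0.39), and Apod, a lipid carrier (-1.53 ± 0.36). The list did not pass (adjusted p = 0.0585). It did without circulating replicate 1 (adjusted p = 0.0416, or 0.0416 to 0.145 over the libraries left out) and with fry (adjusted p = 0.0415). Adjusted over the list alone 1 member was lower without circulating replicate 3, muscle replicate 2 or muscle replicate 3, and with scaling on abundant genes 1 was lower and 2 were higher.

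Collagen genes were lower as a list, with a negative log2 fold change in 21 of 23. Over all genes 1 fell in edgeR (Col15a1) and 11 with DESeq2, and 13 fell adjusted over the list alone. Col1a1, a chain of the main fibrillar collagen, was at 1568 ± 185 CPM in circulating and 4093 ± 179 CPM in muscle FAPs (-1.38 ± 0.21), and Col3a1 at 3435 ± 1016 and 9644 ± 500 CPM (-1.49 ± 0.24). The basement membrane chains Col4a1 (-1.81 ± 0.29) and Col4a2 (-2.10 ± 0.35) fell by the same count. The list was lower than other genes (adjusted p = 3.14e-10; adjusted p = 0.163 with an estimated correlation), with a median of -1.25, or -0.58 with scaling on abundant genes, where 8 members were lower and 1 higher. Between 11 and 16 members were lower when each library was left out.

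Matrix glycoproteins and proteoglycans were also lower as a list, with 2 of 45 members lower over all genes in edgeR (Mgp and Thbs1), 14 with DESeq2 and 14 adjusted over the list alone. Thbs1, a thrombospondin that can activate latent TGF-beta, fell from 476 ± 15.4 to 72.2 ± 27.6 CPM (-2.72 ± 0.39, adjusted p = 0.0349). Adjusted over the list alone, Sparcl1 (-2.70 ± 0.45), Eln, which encodes elastin (-2.21 ± 0.43), and the small leucine-rich proteoglycans Lum (-1.78 ± 0.33) and Dcn (-1.19 ± 0.25) fell. The list was lower than other genes (adjusted p = 3.46e-09; adjusted p = 0.163 with an estimated correlation), with a median of -0.74. With scaling on abundant genes the median was -0.04, and 10 members were lower and 6 higher adjusted over the list alone; with the trend with abundance removed the list did not pass (adjusted p = 0.0501). Among 34 matrix crosslinking and processing enzymes, Adamts1, a metalloproteinase, fell adjusted over the list alone (-1.76 ± 0.34) and over all genes none passed in edgeR and 5 were lower with DESeq2. This list was lower than other genes (adjusted p = 0.000755; adjusted p = 0.218 with an estimated correlation), but with the trend with abundance removed it did not pass (adjusted p = 0.984, on the higher side). Its median of -0.67 became 0.01 with scaling on abundant genes and -0.02 with upper quartile scaling. Its count of 1 became 3 without circulating replicate 1, 0 without muscle replicate 1 and 0 without muscle replicate 3.

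TGF-beta ligands, receptors and targets were lower as a list, with 7 of 30 members lower adjusted over the list alone. None passed over all genes in edgeR and 9 were lower with DESeq2. Tgfbi, a matrix protein induced by TGF-beta, fell from 499 ± 114 to 99.4 ± 27.8 CPM (-2.33 ± 0.38). Ltbp4, which binds latent TGF-beta (-1.70 ± 0.39), and the ligand subunit Inhba (-2.50 ± 0.65) fell too. Among the others that fell were the transcriptional regulators Skil, Tgif1 and Id2. The list was lower than other genes (adjusted p = 4.91e-07; adjusted p = 0.166 with an estimated correlation), with a median of -1.26, or -0.81 without muscle replicate 3 and -0.57 with scaling on abundant genes, where 5 members were lower and 1 higher.

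Growth and neurotrophic factors had 1 of 29 members lower over all genes in edgeR (Gdf10), 7 with DESeq2 and 5 adjusted over the list alone. Igf1, the insulin-like growth factor, fell from 525 ± 74.9 to 138 ± 82.2 CPM (-1.93 ± 0.44), and the neurotrophin Ntf3 (-4.12 ± 0.78), Fgf7 (-2.70 ± 0.76) and the midkine Mdk (-6.00 ± 1.04) fell as well. Against other genes the list was lower (adjusted p = 8.83e-05; adjusted p = 0.163 with an estimated correlation), with a median of -0.73, or -1.40 without circulating replicate 3 and -0.06 with scaling on abundant genes, where 3 members were lower and 1 higher. The count of 5 became 9 without circulating replicate 1, and 1 member was higher without circulating replicate 3 or muscle replicate 1.

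Immediate early and dissociation response genes were lower in circulating FAPs, 1 of 29 over all genes in edgeR (Fosb), 8 with DESeq2 and 13 adjusted over the list alone. The list was written as a measure of RNA quality, as handling and dissociation of cells can induce these genes. Fosb fell from 1257 ± 262 to 294 ± 26.5 CPM (-2.10 ± 0.29), and by the second count Fos (-1.17 ± 0.23), Egr1 (-0.73 ± 0.24) and Nr4a1 (-1.42 ± 0.30) fell. The list was lower than other genes (adjusted p = 5.10e-07; adjusted p = 0.163 with an estimated correlation), with a median of -0.83, or -0.08 with scaling on abundant genes, where 2 members were lower. With the trend with abundance removed it did not pass (adjusted p = 0.0510). The count of 13 became 5 without muscle replicate 1, 7 without muscle replicate 2 and 6 without muscle replicate 3.

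NF-kappaB targets had 6 of 22 members lower adjusted over the list alone. None passed over all genes in edgeR and 5 were lower with DESeq2. Whether handling contributed to the lower NF-kappaB targets and chemokines was not tested. The 6 lower NF-kappaB targets were Nfkbia (-0.87 ± 0.28), Tnfaip3 (-2.30 ± 0.60) and Birc3 (-2.51 ± 0.68), which restrain the pathway or cell death, Nfkb1 (-2.19 ± 0.37), the prostaglandin synthase Ptgs2 (-1.76 ± 0.33) and Ier3 (-1.21 ± 0.33). As a list they were lower than other genes (adjusted p = 0.000234; adjusted p = 0.163 with an estimated correlation), with a median of -0.83, or -0.19 with scaling on abundant genes, where 1 member (Nfkb1) was lower. It did not pass with the trend with abundance removed (adjusted p = 0.0546) or above background (adjusted p = 0.0837). Without muscle replicate 2, 2 members were lower and 1 higher. Chemokines and cytokines had 8 of 28 members lower and 1 higher adjusted over the list alone. None passed over all genes in edgeR, and 10 were lower and 1 higher with DESeq2. Cxcl1, a neutrophil chemoattractant, fell from 2263 ± 265 to 717 ± 214 CPM (-1.66 ± 0.29), and Cxcl12 (-1.54 ± 0.37), Ccl2 (-2.29 ± 0.77) and Il6 (-1.84 ± 0.52) fell, while Ccl6, a chemokine of myeloid cells, rose from 0.997 ± 0.159 to 5.37 ± 3.61 CPM (2.41 ± 0.64). The chemokine list was lower than other genes (adjusted p = 0.00201; adjusted p = 0.166 with an estimated correlation), but its median of -0.60 was 0.06 with scaling on abundant genes and with upper quartile scaling, -1.05 without circulating replicate 1 and -1.22 without circulating replicate 2. With scaling on abundant genes the balance turned, with 4 members higher (Ccl6, Cxcl13, Il1b and Il18) and 2 lower (Cxcl1 and Cxcl2), and with the trend with abundance removed the list did not pass (adjusted p = 0.166). It did not pass without circulating replicate 3 (adjusted p = 0.0656, with 3 higher and 6 lower), 3 members were lower and 0 higher without muscle replicate 2, and 2 were higher without circulating replicate 1.

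**Figure D3:**
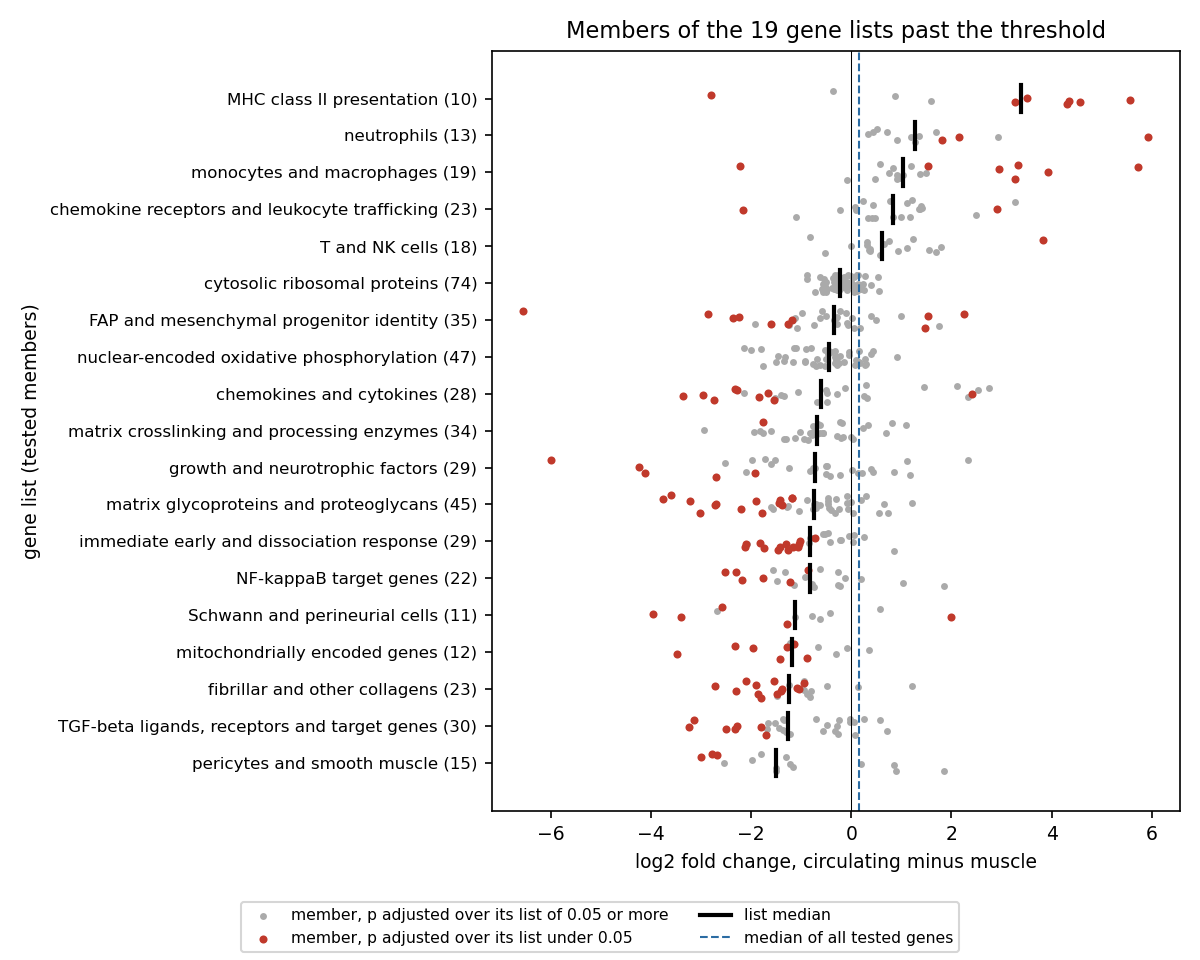
Log2 fold change (circulating minus muscle) of each tested member of the 19 lists past the threshold, with members past the test adjusted over their list alone in red, others in grey and the list median as a black bar. The medians of 5 lists lie above and those of 14 below the dashed line, the median of all tested genes at 0.15; with scaling on abundant genes the medians of the FAP identity, matrix enzyme, chemokine, oxidative phosphorylation and ribosomal protein lists turn positive.

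Genes of antigen presentation by MHC class II were higher in circulating libraries, 6 of 10 adjusted over the list alone. Over all genes none passed in edgeR, while with DESeq2 4 were higher (H2-Aa, H2-Ab1, H2-DMa and Cd74) and 1 lower. H2-Ab1, a class II chain, rose from 3.85 ± 2.64 to 37.4 ± 12.9 CPM (3.28 ± 0.78), with 51.7, 33.7 and 26.7 CPM in circulating replicates 1, 2 and 3. H2-Aa (4.35 ± 1.06), the peptide exchange chains H2-DMa (4.56 ± 1.13) and H2-DMb1 (4.30 ± 1.41), the invariant chain Cd74 (3.51 ± 0.86) and the protease Ctss (5.57 ± 1.62) passed as higher by the same count, while Ifi30, a lysosomal thiol reductase, fell (-2.80 ± 0.60). The list was higher than other genes (adjusted p = 0.00201; adjusted p = 0.163 with an estimated correlation), with a median of 3.39, or 2.02 without circulating replicate 1 and 2.18 without circulating replicate 2. H2-Aa, H2-DMa and H2-DMb1 were uneven among the circulating libraries, at 71.8, 69.2 and 69.2 CPM in replicate 1, 5.59, 4.79 and 2.93 CPM in replicate 2 and 10.4, 8.02 and 0.988 CPM in replicate 3. H2-DMb1 in circulating replicate 3 lay within the muscle range of 0.896 to 1.52 CPM, so its groups overlapped. Ctss was at 1.24, 78.8 and 2.85 CPM in circulating replicates 1, 2 and 3, highest in the library in which 12 of 13 abundant macrophage transcripts exceeded 5 times background. The counts do not tell expression by FAPs from RNA of other cells here.

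Monocyte and macrophage markers were higher as a list (adjusted p = 0.00414; adjusted p = 0.173 with an estimated correlation), with 6 of 19 higher and 1 lower adjusted over the list alone. None passed over all genes in edgeR, and 4 were higher and 1 lower with DESeq2. Csf1r, the receptor for macrophage colony-stimulating factor, was at 8.54, 32.3 and 3.84 CPM in circulating replicates 1, 2 and 3 (2.96 ± 0.90), and the complement gene C1qb at 0.730, 92.9 and 1.10 CPM (5.72 ± 1.83). Cd14, Adgre1, Lyz2 and Cx3cr1 were the other higher members. The list had 12 higher and no lower members with scaling on abundant genes. The count of 6 became 0 without circulating replicate 2, muscle replicate 1, muscle replicate 2 or muscle replicate 3, and no member was lower without muscle replicate 1, muscle replicate 2 or muscle replicate 3. Neutrophil markers were higher as a list (adjusted p = 0.00143; adjusted p = 0.163 with an estimated correlation), with S100a9 (5.93 ± 1.55), Ltf (1.82 ± 0.59) and Il1r2 (2.14 ± 0.68) past the test adjusted over the list of 13 alone. S100a9 was at 69.8, 2.53 and 1.87 CPM in circulating replicates 1, 2 and 3, and the count of 3 became 6 with scaling on abundant genes and 0 without circulating replicate 1, muscle replicate 1, muscle replicate 2 or muscle replicate 3.

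**Figure D4:**
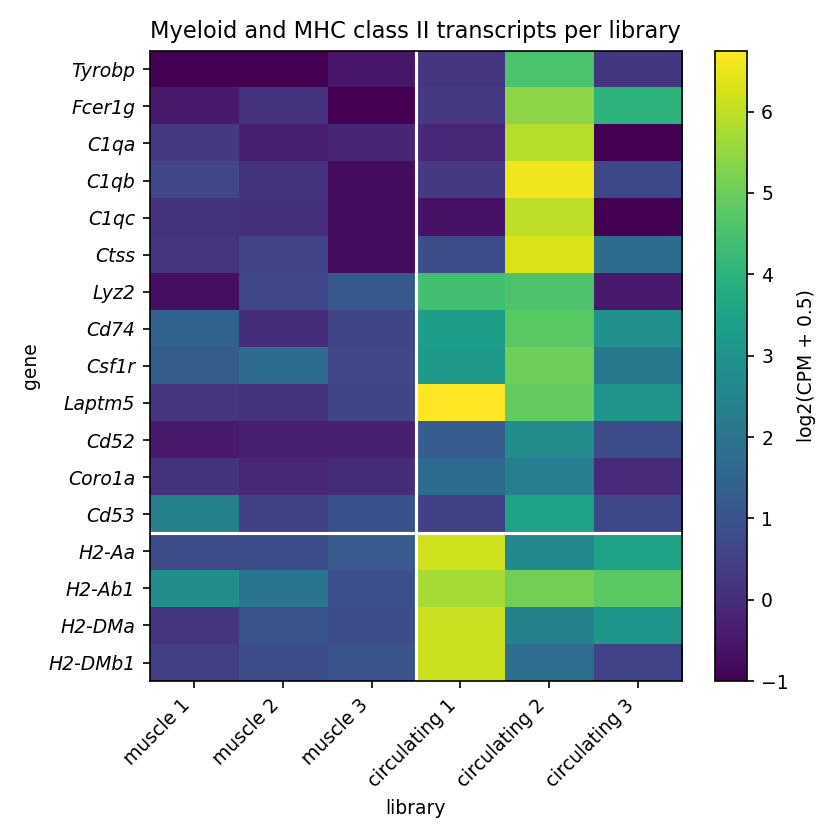
Level of 13 abundant macrophage transcripts (above the white line) and of 4 MHC class II genes (below it) in each library, as log2 of CPM plus 0.5. C1qa, C1qb, C1qc and Ctss are high in circulating replicate 2 (59.0 to 92.9 CPM), and Laptm5, H2-Aa, H2-DMa and H2-DMb1 in circulating replicate 1 (69.2 to 107 CPM).

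Chemokine receptors and leukocyte trafficking genes were higher as a list (adjusted p = 0.0182; adjusted p = 0.257 with an estimated correlation), with the leukocyte integrin Itgb2 higher (2.90 ± 0.68) and the hyaluronan receptor Cd44 lower (-2.17 ± 0.57) of 23 adjusted over the list alone. Scaling on abundant genes gave 8 higher members and 1 lower. The call was lost without circulating replicate 2 (adjusted p = 0.199), without muscle replicate 1 (adjusted p = 0.104) and with the trend with abundance removed (adjusted p = 0.126). Itgb2 and Cd44 did not pass without circulating replicate 2 or any 1 of muscle replicates 1, 2 and 3, and higher members numbered 3 without circulating replicate 1 and 2 without circulating replicate 3, where none was lower. T and NK cell markers were higher as a list of 18 (adjusted p = 0.0331; adjusted p = 0.215 with an estimated correlation), with the perforin gene Prf1 higher adjusted over the list alone, at 2.70 ± 2.30 against 0.180 ± 0.0734 CPM. This call was lost with the trend with abundance removed (adjusted p = 0.702) and without circulating replicate 3 (adjusted p = 0.0656), muscle replicate 1 (0.116) or muscle replicate 3 (0.0596), and Prf1 did not pass without circulating replicate 2, muscle replicate 1, muscle replicate 2 or muscle replicate 3.

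Reads in silent receptor genes, scaled by exon length and library, were 2.82 times as dense in circulating as in muscle libraries. The median circulating level over this background was 17.6 for the MHC class II list and 3.17 for monocytes and macrophages, but 1.84 for neutrophils, 1.87 for chemokine receptors and 1.56 for T and NK cells. It was 48.1 for FAP identity and 38.2 for collagens.

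Pericyte and smooth muscle markers were lower as a list (adjusted p = 0.00201; adjusted p = 0.173 with an estimated correlation), with Rgs5 (41.5 ± 27.7 to 5.20 ± 0.477 CPM), Lmod1 (-2.79 ± 0.71) and Steap4 (-2.69 ± 0.55) lower of 15 adjusted over the list alone. Their median of -1.50 became -0.30 without muscle replicate 3. The count of 3 became 5 without circulating replicate 1 and 1 (Steap4) with scaling on abundant genes, and 1 member was higher without circulating replicate 3. Schwann and perineurial markers were lower as a list of 11 (adjusted p = 0.00771; adjusted p = 0.173 with an estimated correlation). Adjusted over the list alone S100b (-3.96 ± 0.75), Cdh19 (-2.57 ± 0.78), Prx (-3.39 ± 1.27) and Itih5, a hyaluronan-binding protein (-1.29 ± 0.33), fell and 1 member rose. With scaling on abundant genes 1 was lower (S100b) and 1 higher. Itih5 and the pericyte marker Steap4 also stand among the Col15a1/F3-type fibroblast markers compared further below. Itih5 was at 737 ± 194 CPM in muscle and 301 ± 49.5 CPM in circulating libraries. The Schwann call was lost without circulating replicate 1 (adjusted p = 0.155), no member was higher without circulating replicates 1, 2 or 3 or muscle replicates 2 or 3, and 2 members were lower without circulating replicate 2 or circulating replicate 3.

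Mitochondrially encoded genes were lower as a list (adjusted p = 0.000116; adjusted p = 0.210 with an estimated correlation), 7 of 12 adjusted over the list alone. None passed over all genes in edgeR and 4 were lower with DESeq2. CYTB, a subunit of complex III, fell from 3813 ± 1121 to 1424 ± 519 CPM (-1.42 ± 0.32), and ND4, a subunit of complex I, from 1743 ± 648 to 713 ± 190 CPM (-1.29 ± 0.35). The count of 7 became 1 (ND3) with scaling on abundant genes, 4 without circulating replicate 2, 3 without muscle replicate 1 and 4 without muscle replicate 3. Nuclear-encoded oxidative phosphorylation genes were lower as a list of 47 (adjusted p = 0.00143; adjusted p = 0.386 with an estimated correlation) with no single member past either test in edgeR, but 2 lower over all genes with DESeq2 and 8 adjusted over the list alone without circulating replicate 1. Their median of -0.45 became 0.24 with scaling on abundant genes and -0.86 without circulating replicate 1, and with the trend with abundance removed the list did not pass (adjusted p = 0.250, on the higher side). Cytosolic ribosomal protein genes were lower as a list of 74 (adjusted p = 0.0258; adjusted p = 0.702 with an estimated correlation), again with no member past either test in edgeR, and their median of -0.23 became 0.44 with scaling on abundant genes, where 4 members were higher. That median was -0.80 without circulating replicate 1, -0.05 without circulating replicate 2, -0.15 without muscle replicate 1 and -0.36 without muscle replicate 2. The ribosomal call was lost without circulating replicate 2 (adjusted p = 0.382) and without muscle replicate 1 (adjusted p = 0.0748), 26 members were lower without circulating replicate 1, and the list was higher than other genes once the trend with abundance was removed (adjusted p = 4.89e-10; up to 0.702 over the settings tried).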

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

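The tests of the read background, of depth and of macrophage RNA were chosen only after the results were seen.

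Reads in chemosensory receptor genes, which no comparison of gene groups used and which are silent outside sensory tissue, averaged 6786.3 reads per 1000000 (without 18S) in circulating libraries, against 2526 ± 564 in muscle libraries (SD, n = 3). Circulating replicates 1, 2 and 3 had 5499, 8873 and 5987. If such reads were spread evenly over annotated exons, they would make up an estimated 9.53% ± 1.80 of non-18S reads in circulating and 3.38% ± 0.684 in muscle libraries.

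Fold changes fell with abundance, from a median of 0.77 under 2 CPM to -0.65 at 20 CPM and above. Lower depth of the circulating libraries is argued against as the whole cause, since the difference between the medians was 1.41 as deposited and 1.46 after thinning to equal totals without 18S. These differences do not cover the same genes, as 20248 genes were tested as deposited and 14264 after thinning. A read background that is larger in the circulating libraries may contribute, as the receptor density was 2.82 times that of muscle libraries, higher in each circulating than in each muscle library. Background reads would raise rare genes, and the source of these reads was not tested. A difference between blood and muscle FAPs in how many genes are active remains open and untested.

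MHC class II genes were higher as a list in circulating libraries (adjusted p = 0.00201, but 0.163 with an estimated correlation), at a median of 17.6 times the expected background (6.21 to 22.2 times in single circulating libraries), which argues against background reads as the source of the list's rise. RNA of macrophages in circulating replicate 2 may account for its share, as 12 of 13 abundant macrophage transcripts exceeded 5 times background there, with C1qb at 92.9, Ctss at 78.8, C1qc at 62.8 and Tyrobp at 23.2 CPM. In circulating replicates 1 and 3 the counts were 3 and 4 of 13. The test was set for both libraries together, with at most 3 in each as the bound against macrophage RNA; replicate 1 met it and replicate 3 did not, so macrophage RNA and expression by FAPs cannot be told apart over the pair. In replicate 1 H2-Aa was at 71.8, Laptm5 at 107 and Lyz2 at 20.7 CPM, but Tyrobp at 0.657 and C1qb at 0.730 CPM. The neutrophil marker S100a9 was also highest in this library. RNA of leukocytes other than macrophages was not tested as a source. Muscle replicates 1, 2 and 3 had 2, 0 and 1 of 13. Members such as C1qb and Laptm5 also stand in the fixed lists, and Cd74 and Ctss stand in the MHC class II list itself. In circulating replicate 3 Cd74 (10.4 times background) and Ctss (5.15 times) were among the 4, and in replicate 1 Cd74 (11.8 times) was among the 3. The test thus rests in part on the genes whose rise it was to explain. The labels describe no sort, and one that excludes CD45-positive cells would remove macrophages but not free RNA.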

How the results depend on the processing

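Removal of 18S, scaling on abundant genes, restriction to genes above background, thinning without 18S and removal of the trend with abundance were chosen only after the results were seen. The 22 genes kept their sign in each setting that tested them. Where the count moved by over 1.5 times, genes past the threshold numbered 43 with RLE size factors (42 lower), 2 with upper quartile scaling (1 higher, 1 lower), 160 without a filter (6 higher, 154 lower), 1524 with DESeq2 (160 higher, 1364 lower), 93 with voom (2 higher, 91 lower), 7 with scaling on abundant genes (3 higher, 4 lower), and 1 (0 higher, 1 lower) with a test against a log2 change of 1 and at a threshold of 0.01. The count with the replicate number as a replicate block was 1 (0 higher, 1 lower), where the block takes degrees of freedom. Correlations of same-numbered muscle and circulating residual profiles were 0.008, 0.041 and 0.006, and muscle replicates 1, 2 and 3 correlated best with circulating replicates 1, 2 and 1. Higher genes alone moved to 2 with library size scaling, 5 with the filter of 5 CPM and 6 above background. Leaving out each library gave 0 to 65 genes, 0 to 2 higher and 0 to 63 lower; these fits rest on fewer samples. Lists past the threshold numbered 0 (0 higher, 0 lower) with an estimated correlation, 11 with the filter of 5 CPM (7 lower), 8 above background (4 lower) and 11 with the trend with abundance removed (6 lower), of which 9 kept their direction; fewer genes were tested with the filter and above background, and the cause was not tested otherwise. Leaving out each library gave 17 to 20 lists, 3 to 5 higher (3 without muscle replicate 1) and 13 to 15 lower. With fry 4 lists were no longer past the threshold, those of chemokine receptors, ribosomal proteins, monocytes and oxidative phosphorylation (adjusted p = 0.0583 to 0.559). Another 4 passed with fry, the adipogenic (0.0415), B cell (0.0374), haematopoietic stem and progenitor (0.0401) and satellite cell (0.0209) lists. The replicate block and RLE size factors changed no list call. With the filter of 5 CPM the FAP identity, matrix enzyme, chemokine receptor, oxidative phosphorylation, mitochondrial, monocyte, pericyte and Schwann lists lost their calls (adjusted p = 0.0834 to 0.926), and muscle fibres (0.0170) and tenocytes (0.0191) were higher; the neutrophil and T and NK cell lists had too few members to test there. Above background these and the chemokine receptor and Schwann lists also had too few members to test. The mitochondrial list could not be tested either, as its symbols had no exon length, which makes 5 of the 19. Of the others the FAP identity, glycoprotein, matrix enzyme, chemokine, NF-kappaB, immediate early and oxidative phosphorylation lists lost their calls above background (adjusted p = 0.0615 to 0.990), and tenocytes were higher (0.0473). Scaling on abundant genes ended the ribosomal protein call (0.591). Cytosolic ribosomal protein genes turned higher with the filter of 5 CPM (adjusted p = 0.0170), above background (adjusted p = 7.10e-05) and with the trend removed (adjusted p = 4.89e-10); the cause was not tested. The 18S share differed by 18.2 percentage points, or 14.6 with 18S reads counted once, a setting chosen only after the results were seen. With 18S left out, the difference circulating minus muscle was 0.0297 percentage points for haemoglobin, 2.43 for ribosomal protein, -0.381 for mitochondrial transcripts, whose groups then overlapped, and -3.28 for the 10 most abundant genes, as the totals no longer hold 18S. The difference in detected genes was 3090 at 5 reads, -206.3 without thinning and 2504 without 18S. Depth limits rare genes most: circulating replicate 2 had 3106011 counts other than 18S.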

Other observations

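The split counts and the comparison of mean log2 fold changes of FAP subtypes were planned before their results were seen; scaling on abundant genes, restriction to genes above background and removal of the trend with abundance were chosen only after the results were seen.

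C3, the central complement component, was at 2091 ± 207 CPM in circulating and 1057 ± 120 CPM in muscle FAPs (0.98 ± 0.24, SE, n = 3 per group; adjusted p = 0.130 in edgeR). Adjusted over the list of 16 complement genes alone 1 member, C3, was higher and 1 was lower, and the list did not pass (adjusted p = 0.177). The counts of 1 higher and 1 lower became 4 and 5 without circulating replicate 1, 4 and 2 without circulating replicate 3, 0 and 1 without muscle replicate 1, muscle replicate 2 or muscle replicate 3, and 2 and 1 with scaling on abundant genes. Above background, C3 (1.65 ± 0.19), Efemp1, Dpp4, Laptm5, Sema3c, which encodes a secreted semaphorin (1.69 ± 0.29), and Gm10222 were higher among 23 genes past the threshold. Interferon-stimulated genes did not pass as a list of 33 (adjusted p = 0.137), and Ifit3 fell adjusted over the list alone, from 71.6 ± 9.28 to 3.89 ± 2.29 CPM (-4.21 ± 0.67), with 2 lower without circulating replicate 1 or muscle replicate 1.

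Among lysosome and phagocytosis genes, Laptm5, a lysosomal protein of blood cells, rose adjusted over the list of 28 alone (5.96 ± 1.07), and the list did not pass (adjusted p = 0.422; its mean was positive and its median negative). Laptm5 did not pass without muscle replicate 1 or muscle replicate 2, and 4 members were lower without circulating replicate 1. Platelet and megakaryocyte markers did not pass as a list of 12 (adjusted p = 0.801; its median was positive and the test on the lower side), and Gp9 fell adjusted over the list alone (-3.57 ± 0.80) but did not pass with scaling on abundant genes. In edgeR with TMM scaling no member passed adjusted over the list alone for cell cycle (list adjusted p = 0.737), glycolysis (0.0785), erythroid (0.411), B cell (0.301), haematopoietic stem and progenitor (0.295), endothelial (0.315), satellite cell (0.351), muscle fibre (0.454) and tenocyte (0.560) genes. None of these lists passed with camera. With fry the B cell (adjusted p = 0.0374), haematopoietic stem and progenitor (0.0401) and satellite cell (0.0209) lists passed. With scaling on abundant genes 5 haematopoietic stem and progenitor genes (Kit, Flt3, Procr, Myb and Tal1), 5 tenocyte genes and 3 satellite cell genes were higher adjusted over their list alone. Under that scaling the list medians were 1.07, 1.05 and 1.27, against 1.45 for all genes under 2 CPM. The median circulating level over background was 1.46 for the haematopoietic and 1.38 for the satellite cell list, against 15.5 for tenocytes. Procr also stands among the Dpp4/Pi16-type fibroblast markers compared below. With the trend with abundance removed the tenocyte list was higher than other genes (adjusted p = 0.00973). Without that removal it did not pass (adjusted p = 0.560, or 0.702 with an estimated correlation). Lists that did not pass and whose negative median turned positive with scaling on abundant genes were adipogenic (0.29), interferon (0.62), complement (0.61), lysosome (0.53), glycolysis (0.19), endothelial (0.29) and cell cycle (0.63). Glycolysis passed without circulating replicate 1 (adjusted p = 0.0416) and without muscle replicate 2 (adjusted p = 0.0403), with 1 lower member without circulating replicate 3. Endothelial genes passed without muscle replicate 1 (adjusted p = 0.00878, 1 member lower). Without circulating replicate 2, 1 satellite cell gene was higher and 2 tenocyte genes were higher and 1 lower, and 1 tenocyte gene was higher without circulating replicate 1.

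Circulating FAPs may hold a different mix of FAP subtypes from muscle, a hypothesis raised by Dpp4 and Pi16 being higher and Col15a1 and F3 lower. It was tested on 25 other markers of Dpp4/Pi16-type fibroblasts and 21 of Col15a1/F3-type ones, whose mean log2 fold changes differed by 2.07 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; genes are not independent). Positive values were found for 18 of 25 and 1 of 21 markers, and over all genes none passed in edgeR, while 1 Dpp4/Pi16-type marker was higher and 11 Col15a1/F3-type markers were lower with DESeq2. With the trend with abundance removed, which was not planned, the difference was 1.99, and 25 and 7 markers were positive. Leaving out the 5 and 9 markers that also stand in the fixed lists, the planned difference was 2.06. A change of these genes within cells gives the same values as a change of mix, and bulk counts do not separate them.

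Of the 10 splits of the 6 samples 3 against 3, 1, the real one, gave 22 genes, and the highest of the others gave 0. For lists 1 split, the real one, gave 19, and the highest of the others gave 11. So few splits do not allow a share under 0.05.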
